A study of Homo sapiens with 16 samples.

How the data were processed

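The material was 16 RNA-seq libraries of human ARPE-19 cells, 8 from a line with RRBP1 tagged at its endogenous locus by GFP11 and 8 from a line with MTA2 tagged in that way, both with GFP1-10 in mitochondria. Each line had 4 groups of 2 libraries: inactive ApaLI unsorted, active ApaLI unsorted, active ApaLI sorted as GFP−, and active ApaLI sorted as GFP+, all after 3 days of doxycycline. Per the labels' protocols, RNA with integrity numbers of 8.9 to 10 (500 ng) went into poly(A)-selected stranded libraries with 8 PCR cycles.

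The values analysed were the raw read counts per gene symbol that the authors deposited, as a table for each line with 59385 symbols each, of which 38456 match RefSeq symbols. Per the submitters' processing notes STAR and DESeq2 were used; versions, genome build, annotation and the way of counting are not given in the sources used here. The tables hold no transgene. How reads over overlapping genes were counted is likewise not given in the sources used here, which bears on ASNS, GDF15 and FGF21, whose counts were low; FGF21 was not tested. Nuclear copies of mtDNA share reads with mtDNA genes.

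Library depth ran from 24767861 to 31187566 counts in the RRBP1 line and from 39251584 to 56005841 in the MTA2 line. The biological coefficient of variation was 3.92% in the RRBP1 fit, 8.18% in the MTA2 fit and 6.54% in the fit of both lines. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8). In each line, genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and one model with the 4 groups was fitted. Contrasts were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at an adjusted p under 0.05. CPM are TMM-scaled.

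Before the data were examined, 4 main comparisons were fixed: active against inactive ApaLI in unsorted cells and GFP+ against GFP− cells, in each line. Line differences of each effect were tested as interactions in a joint fit of 17082 genes. Library names carry a different code in each line. The tag, the cells of the line and any difference in handling therefore cannot be told apart. GFP− and GFP+ cells against inactive ApaLI were secondary, since sorted cells were set against unsorted ones and these comparisons share control libraries. GFP− and GFP+ against unsorted active cells were added after seeing the data. The labels share only replicate numbers, which does not establish pairs, so the fits are unpaired.

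The gene lists, also fixed before the data were examined, numbered 31: ISR regulators, serine and one-carbon enzymes, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, mitochondrial chaperones and proteases, ER unfolded protein response, interferon-stimulated genes, NF-kB and secreted inflammatory genes, mtDNA-encoded protein genes, nuclear OXPHOS subunits, mitochondrial ribosomal proteins, mtDNA maintenance and transcription, mitochondrial cristae and dynamics, eIF2alpha kinases, p53 target genes, mitosis genes, DNA replication genes, replication-dependent histone genes, cholesterol synthesis genes, fatty acid synthesis genes, hypoxia and glycolysis genes, NRF2 target genes, autophagy and lysosome genes, BCL2 family genes, immediate-early genes, heat shock genes, cytosolic ribosomal proteins, extracellular matrix and contractile genes, retinal pigment epithelium markers, blood and immune cell markers, and neural and photoreceptor markers. Each was tested by limma's camera with a preset correlation between genes of 0.01, adjusted over the 31 lists of a contrast, and again with the correlation estimated from the data. Genes in a list were also adjusted over the list alone. The libraries were poly(A)-selected, so values of histone genes cover polyadenylated transcripts and do not measure total histone RNA.

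Named genes followed a rule set before the data were examined. It took the 10 highest and 10 lowest passing genes of each main comparison with a mean of at least 5 CPM, a plain symbol and both libraries of one group above both of the other. For line differences it took 5 each way, and there the condition on both libraries was not applied. It also took up to 4 members of each list with the smallest adjusted p, and a fixed set with RRBP1, MTA2, ATF4, DELE1 and the mtDNA protein genes. Genes outside it are said to be chosen after their values were seen.

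The test was checked on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 67 and 83 of them in the RRBP1 ApaLI comparison, 43 and 74 in the MTA2 ApaLI comparison, 75 and 88 in the RRBP1 GFP comparison, 53 and 78 in the MTA2 GFP comparison, and 41 and 67, then 40 and 60, for the line differences. False calls made up 3.85%, 10.0%, 6.32%, 7.09%, 2.70% and 6.54% of calls in that order. A list of 20 genes raised 1.5-fold was called and 0 of 30 unchanged lists were called in each. The simulated genes were drawn independently, so this does not check the list test under correlation between genes. Chi-square over degrees of freedom between replicates, over genes with at least 20 counts, was 2.55, 4.21, 2.74 and 4.43 in the RRBP1 groups (inactive, active, GFP−, GFP+) and 33.8, 11.1, 12.2 and 3.22 in the MTA2 groups, so no pair was as close as sampling noise alone.

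Alternatives tried were DESeq2 size factors, library totals only, mtDNA genes removed before scaling, no count filter, a filter of 1 CPM in 2 libraries, DESeq2's Wald test, the replicate number as a block, an added 2-fold threshold, leaving out each library, the 4 compared libraries alone, all 16 in one fit, an estimated correlation for camera, and fry. Splicing, variants and transgene levels were not analysed here. Sex-linked genes were not examined as a group, and they were not removed from the fits or lists. A single gene that the rule names is not reported.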

Results

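Poly(A) RNA was sequenced from human ARPE-19 retinal pigment epithelial cells that expressed the restriction enzyme ApaLI in mitochondria, where it breaks mitochondrial DNA (mtDNA), or an inactive form of it. A GFP fragment was fused to endogenous RRBP1 in one line and to MTA2 in the other, and its partner fragment sat in mitochondria, so that green cells are those in which the fragments met. After 3 days of doxycycline each line gave 4 groups of n = 2 libraries: unsorted cells with inactive ApaLI, unsorted cells with active ApaLI, and sorted GFP− and GFP+ cells with active ApaLI. Libraries held 24767861 to 31187566 counts in the RRBP1 line and 39251584 to 56005841 in the MTA2 line. The labels do not say whether the replicates came from separate cultures, so every p-value measures only the spread between these samples.

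What did active ApaLI do to mtDNA transcripts? Those that encode proteins collapsed in both lines, while counts of ribosomal RNA fell less or not at all. The libraries were poly(A)-selected, so counts of ribosomal RNA do not measure its total amount. The share of all counts from mtDNA, ribosomal RNA included, was 6.46 ± 0.117% (SD, n = 2) with inactive and 0.377 ± 0.0158% (SD, n = 2) with active ApaLI in unsorted RRBP1-tagged cells, and 5.59 ± 0.501% against 0.453 ± 0.0849% (SD, n = 2) in MTA2-tagged cells. MT-ND4 fell from 10305 ± 341 to 268 ± 13.8 CPM (SD, n = 2) in the RRBP1 line, a log2 fold change of −5.26 ± 0.06 (SE), and MT-CO1 changed by −4.58 ± 0.06 and, in the MTA2 line, by −3.93 ± 0.15. MT-ND6, the one protein gene on the light strand, fell with the rest (−4.96 ± 0.13 in the MTA2 line). All 13 mtDNA protein genes passed as lower in both lines, also when adjusted over the list alone, with medians of −5.18 (RRBP1) and −4.64 (MTA2). The ribosomal RNAs, chosen after their values were seen, moved less. MT-RNR1 stood at 656 ± 0.429 with inactive and 763 ± 23.9 CPM (SD, n = 2) with active ApaLI in the RRBP1 line (0.22 ± 0.04, SE, not past the threshold with all 16 libraries in one fit, adjusted p = 0.0517 by edgeR), and at 1218 ± 111 and 743 ± 21.8 CPM (SD, n = 2) in the MTA2 line (−0.71 ± 0.07, SE). MT-RNR2 fell by −2.21 ± 0.04 in the RRBP1 line, from 5012 ± 84.7 to 1082 ± 52.4 CPM (SD, n = 2), and from 4960 ± 561 to 1473 ± 232 CPM (SD, n = 2) in the MTA2 line. The camera test on the protein genes passed in both (adjusted p = 2.46e-05 and 0.00141 with an estimated correlation). Nuclear copies of mtDNA share reads with these genes, so the lowest levels are uncertain.

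**Figure D1:**
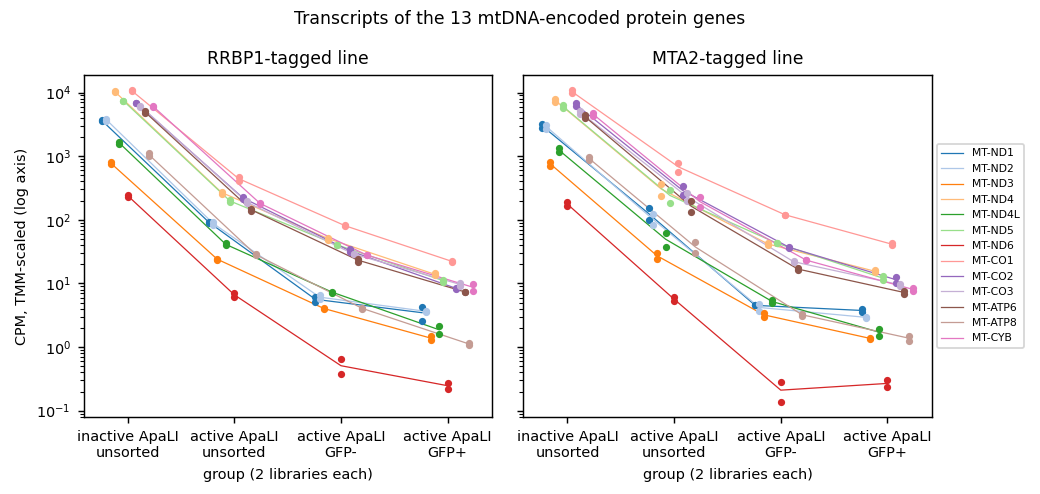
CPM of the 13 mtDNA-encoded protein genes in each group of both lines, with both libraries of each group.

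Which nuclear genes answered active ApaLI in the RRBP1 line? The p53 targets rose as a group. CDKN1A rose from 91.8 ± 1.65 to 245 ± 11.2 CPM (SD, n = 2, log2 fold change 1.41 ± 0.05, SE; adjusted p = 1.74e-17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and BTG2 (1.69 ± 0.12), TP53INP1, BBC3, RRM2B (0.82 ± 0.05) and ZMAT3 rose with it. Of 27 tested p53 targets 19 rose, 1 fell and 7 did not pass (23 and 1 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 2.53e-26, adjusted p = 0.0174 with an estimated correlation). RIMS1 (1.88 ± 0.12, 3.67-fold), PTCHD4, PPL, the hypoxia gene CA9 (1.32 ± 0.08), ERBB4, SLC44A5, FAXDC2 and KRT33B completed the 10 highest genes. The 10 lowest were mtDNA genes; among passing nuclear genes with a mean of at least 5 CPM, chosen after their values were seen, COL1A1, CSRP1 (−0.82) and HLA-F (−0.81) were lowest.

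Proliferation genes fell slightly in the same cells. Of 28 mitosis genes 22 were lower, 0 higher and 6 did not pass (25 lower over the list alone, median −0.23, camera adjusted p = 7.49e-08, adjusted p = 0.63 with an estimated correlation), PLK1 and CDC20 among them. Without inactive replicate 2 the count was 9, and without active replicate 1 it was 11. Of 28 DNA replication genes 12 were lower, 0 higher and 16 did not pass (21 lower over the list alone, median −0.17, camera adjusted p = 0.000161, adjusted p = 0.63 with an estimated correlation). That count was 3 without either inactive replicate, 5 without active replicate 1 and 7 without active replicate 2. Of the 19 tested regulators of the integrated stress response (ISR), the programme in which ATF4 answers phosphorylated eIF2α, 2 rose, 4 fell and 13 did not pass (2 and 5 over the list alone). Their median was −0.11, their mean 0.02 and the test pointed down (camera adjusted p = 0.816). TRIB3 fell from 50.4 ± 1.58 to 38.1 ± 0.179 CPM (SD, n = 2, −0.40 ± 0.06, SE), while ATF4 (0.08), CHAC1 (−0.25), DDIT3 (0.12) and the low-count ASNS (0.03) did not pass. The ISR genes that fell numbered 2 without either inactive replicate or active replicate 2, and those that rose numbered 1 without inactive replicate 2.

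Across all genes of the RRBP1 line, 827 were higher and 900 lower of 15463 tested, 85 and 57 of them at least 2-fold; scaled by library totals alone the split was 2281 and 298. Without one library the count was 834 (inactive replicate 1), 703 (inactive replicate 2) or 1076 (active replicate 2). None of the genes proposed to relay mitochondrial stress to eIF2α passed: DELE1 −0.06, OMA1 0.04 and EIF2AK1 0.06. ISG15 (−0.15), IFIT1 (0.20), TFAM (−0.07), HSPD1 (−0.03) and HSPA5 (0.14) did not pass either.

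Did the MTA2 line answer in the same way? It shared the p53 response, and the ISR list rose there. For CHAC1 and TRIB3 the rise began below the RRBP1 line's inactive level and ended no higher than its active level. CDKN1A rose from 48.1 ± 6.60 to 185 ± 15.2 CPM (SD, n = 2, 1.94 ± 0.10, SE), BTG2 by 1.91 ± 0.09, RRM2B by 1.12 ± 0.08 and FDXR by 1.61. Of 27 p53 targets 18 rose, 0 fell and 9 did not pass (22 over the list alone), with a median of 0.66 (camera adjusted p = 1.97e-52, adjusted p = 0.00141 with an estimated correlation). CHAC1, an ATF4 target, rose from 2.74 ± 0.0495 to 9.08 ± 0.712 CPM (SD, n = 2, 1.73 ± 0.12, SE), SESN2 by 1.17 ± 0.09, and the amino acid genes SLC6A9 by 1.60 ± 0.12 and CTH by 1.02 ± 0.08.

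Of 19 ISR regulators in that comparison 8 rose, 0 fell and 11 did not pass (13 over the list alone), with a median of 0.47 (camera adjusted p = 1.24e-15, adjusted p = 0.0488 with an estimated correlation). The count was 3 without active replicate 1 and 4 without active replicate 2. ATF4 (0.32, adjusted p = 0.0159) lost its call without active replicate 1 (0.0869) or 2 (0.0910), and so did TRIB3 (0.59, 0.0120, then 0.109 and 0.0502). DDIT3 (0.37) and ASNS (1.08, from 0.450 CPM) did not pass, nor did DELE1 (0.12), OMA1 (−0.29) or EIF2AK1 (0.04). Of 18 amino acid synthesis and transport genes 5 rose, 0 fell and 13 did not pass (8 over the list alone, median 0.31, camera adjusted p = 1.26e-07, adjusted p = 0.0839 with an estimated correlation). That count was 2 without either active replicate and 9 without inactive replicate 1.

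Matrix genes rose in MTA2-tagged cells: of 24 extracellular matrix and contractile genes 12 rose, 0 fell and 12 did not pass (16 over the list alone, median 0.49, camera adjusted p = 1.78e-25, adjusted p = 0.00302 with an estimated correlation). TGFBI (0.73 ± 0.06), THBS1 (0.71) and POSTN (1.82 ± 0.18) were among them, and IGFBP3 rose from 140 ± 3.30 to 441 ± 32.9 CPM (SD, n = 2, 1.65 ± 0.08, SE). PTCHD4 (2.18 ± 0.14), CDH10, IGFBP5, SULF2 and DDIT4 were also among the 10 highest genes. The 10 lowest passing nuclear genes with a mean of at least 5 CPM, chosen after their values were seen, included ABCB5 (−1.49 ± 0.13), PCDH7, HSD17B2, MAP2 and PPARGC1A (−0.96 ± 0.10), a coactivator of mitochondrial biogenesis.

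Sterol and interferon genes lay lower in the same comparison. Of 23 cholesterol synthesis genes 7 fell, 0 rose and 16 did not pass (14 over the list alone, median −0.26, camera adjusted p = 2.42e-10, adjusted p = 0.119 with an estimated correlation), with INSIG1 at −0.66 and HMGCS1 at −0.59. The count was 4 without active replicate 1, 3 without active replicate 2 and 11 without inactive replicate 1. Of 36 interferon-stimulated genes 8 fell, 0 rose and 28 did not pass (12 over the list alone, median −0.33, camera adjusted p = 9.39e-09, adjusted p = 0.201 with an estimated correlation). None of the 8 was left without active replicate 1, and 1 without active replicate 2. ISG15 (−0.22) and IFIT1 (−0.12) did not pass. Across the MTA2 line 282 genes were higher and 281 lower of 17198 tested (428 and 213 scaled by library totals). The count of 563 was 3304 without inactive replicate 1, 200 without active replicate 1 and 160 without active replicate 2.

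Did active ApaLI act differently in the lines? The fold change differed for 414 of 17082 genes, higher in the MTA2 line for 135 and lower for 279, a split that turned to 1822 and 851 without MTA2 inactive replicate 1 and to 760 and 420 without a count filter. CHAC1 differed by 1.97 ± 0.18 (adjusted p = 4.2e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), TRIB3 by 0.98 and the amino acid gene SLC6A9 by 1.75. With inactive ApaLI, CHAC1 stood at 13.9 and 2.74 CPM and TRIB3 at 50.4 and 23.1 CPM (RRBP1, MTA2). With active ApaLI they stood at 11.7 and 9.08 CPM and at 38.1 and 34.8 CPM, so the inactive levels differed more. ATF3 was higher in the MTA2 line in both, at 4.27 and 5.18 CPM with inactive and 5.46 and 8.23 CPM with active ApaLI. The lines were scaled apart for these CPM, and a difference in library handling between the lines would not cancel in them. The ISR list differed by a median of 0.51 (7 higher, 0 lower, 12 not passed; 13 and 1 over the list alone, camera adjusted p = 1.01e-17, adjusted p = 0.00496 with an estimated correlation). Matrix and contractile genes differed by a median of 0.49 (10 higher, 0 lower, 15 not passed, 13 over the list alone, camera adjusted p = 1.01e-17, adjusted p = 0.00277 with an estimated correlation). The ApaLI effect was higher in the MTA2 line for IGFBP5 (1.71) and TAGLN (1.56). It was lower there for HSD17B2 (−2.41), PCDH7 (−2.17), SLC7A8 (−2.06) and RIMS1 (−1.79). RIMS1 had log2 fold changes of 1.88 and 0.10 (RRBP1, MTA2), but the others had opposite signs. These were IGFBP5 (−0.11, 1.61), TAGLN (−0.67, 0.90), HSD17B2 (1.07, −1.33), PCDH7 (0.80, −1.36) and SLC7A8 (1.10, −0.95). MMP2 (2.05, adjusted p = 0.0460) lost its call without any one of 5 libraries (0.302 without RRBP1 inactive replicate 1, the highest). CDKN1A differed by 0.51 (adjusted p = 0.0199). The count ran from 141 without RRBP1 inactive replicate 2 to 2673 without MTA2 inactive replicate 1. The fold changes of 15314 genes correlated at r = 0.419 (Spearman 0.0921; genes are not independent replicates), and at 0.179 without mtDNA genes. Of 213 genes called in both lines 113 were higher and 67 lower in both, where 14.7 and 15.6 were due by chance. The other 33 went opposite ways, about as many as were due by chance (30.4). The 67 include the 13 mtDNA protein genes.

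How did GFP+ cells differ from GFP− cells of the RRBP1 line? The ISR was raised in them. TRIB3 rose from 34.1 ± 1.70 to 155 ± 6.67 CPM (SD, n = 2, 2.18 ± 0.06, SE), CHAC1 from 9.50 ± 1.15 to 37.4 ± 1.54 CPM (1.98 ± 0.10), DDIT3 from 19.1 ± 0.208 to 44.5 ± 1.45 CPM (1.22 ± 0.07) and ATF4 from 364 ± 7.68 to 489 ± 1.48 CPM (0.43 ± 0.04; adjusted p = 8.73e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 19 ISR regulators 17 rose, 0 fell and 2 did not pass (17 over the list alone, median 0.85, camera adjusted p = 2.23e-22, adjusted p = 0.0274 with an estimated correlation). Of 18 amino acid genes 15 rose, 0 fell and 3 did not pass (15 over the list alone, median 0.67, camera adjusted p = 1.19e-16, adjusted p = 0.0274 with an estimated correlation), with SLC6A9 at 2.56 ± 0.10 and CTH at 2.39 ± 0.08. ASNS rose by 2.34 ± 0.20 from a low 1.20 CPM. Of 20 aminoacyl-tRNA synthetases 11 rose, 0 fell and 9 did not pass (11 over the list alone, median 0.22, camera adjusted p = 2.59e-08, adjusted p = 0.118 with an estimated correlation), WARS1 and GARS1 among them.

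**Figure D2:**
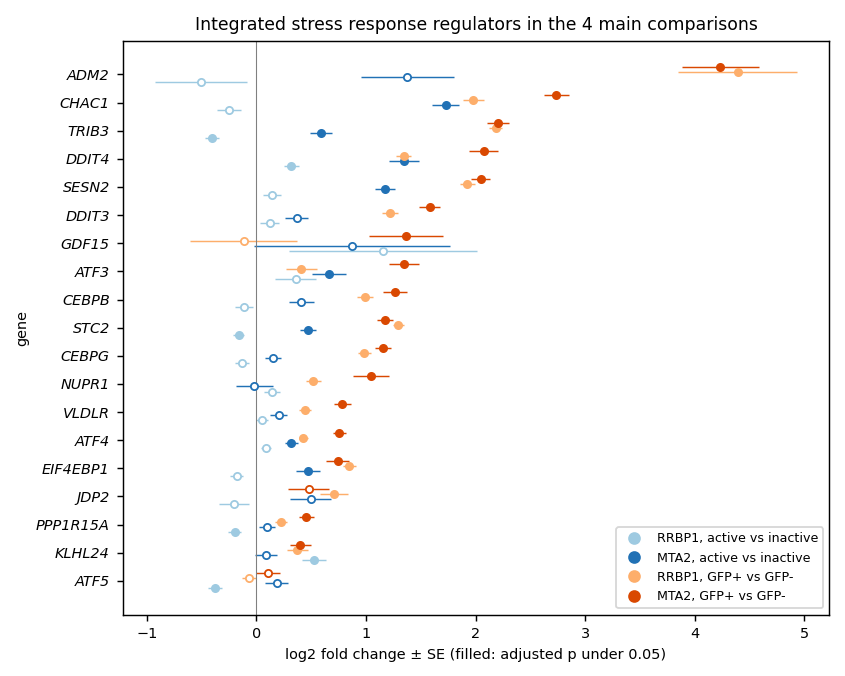
Log2 fold change and SE of each integrated stress response regulator in the main comparisons of both lines, filled where the adjusted p was under 0.05.

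The endoplasmic reticulum arm rose with it in RRBP1-tagged cells. HSPA5 rose from 848 ± 83.1 to 1424 ± 13.4 CPM (SD, n = 2, 0.75 ± 0.05, SE), and of 21 genes of the unfolded protein response 15 rose, 0 fell and 6 did not pass (15 over the list alone, median 0.26, camera adjusted p = 9.55e-07, adjusted p = 0.155 with an estimated correlation). DELE1 (0.04) and OMA1 (−0.15) did not pass; EIF2AK1 (−0.13, adjusted p = 0.0311) lost its call without any one of the 4 libraries (0.208 without GFP− replicate 1, the highest) and by library totals (0.109). PAPPA2 (4.79 ± 0.15, 27.7-fold), the lipase inhibitor ANGPTL4 (4.68 ± 0.24), PTX3, SULF2, SLFN5 and PID1 were also among the 10 highest genes. Of 21 NRF2 targets 14 rose, 0 fell and 7 did not pass (15 over the list alone, median 0.38, camera adjusted p = 1.09e-05, adjusted p = 0.073 with an estimated correlation), HMOX1 among them.

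GFP+ cells of the RRBP1 line carried far less cell cycle RNA. KIF20A fell by −2.66 ± 0.07, 6.30-fold, and PIF1, NMU, CENPA, NEURL1B, NEK2, TROAP, DLGAP5 and PLK1 (−2.43) were among the 10 lowest genes. All 28 mitosis genes were lower (28 over the list alone, median −2.10, camera adjusted p = 1.07e-163, adjusted p = 0.0274 with an estimated correlation), and so were 27 of 28 DNA replication genes, with 1 not passed (27 over the list alone, median −1.25, camera adjusted p = 3.8e-59, adjusted p = 0.0274 with an estimated correlation). CDKN1A rose from 327 ± 9.95 to 786 ± 8.72 CPM (SD, n = 2, 1.27 ± 0.05, SE). Of 27 p53 targets 22 rose, 2 fell and 3 did not pass (22 and 2 over the list alone, median 0.50, camera adjusted p = 1.64e-10, adjusted p = 0.0461 with an estimated correlation). Across all genes 3215 were higher and 3538 lower, 378 and 638 of them at least 2-fold; scaled by library totals the split turned to 3737 and 3132.

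Mitochondrial transcripts were lower in GFP+ than in GFP− cells. MtDNA, ribosomal RNA included, gave 0.246 ± 0.00234% of counts in GFP− and 0.0580 ± 0.0000638% (SD, n = 2) in GFP+ cells of the RRBP1 line, and 0.315 ± 0.00402% and 0.118 ± 0.00607% (SD, n = 2) in the MTA2 line. Most of this was ribosomal RNA: protein genes gave 0.0310% and 0.0325% of counts in the GFP− and 0.00987% and 0.00953% in the GFP+ libraries of the RRBP1 line. There MT-RNR1 fell from 860 ± 15.2 to 150 ± 2.30 CPM and MT-RNR2, chosen after its values were seen, from 1243 ± 19.9 to 312 ± 1.73 CPM (SD, n = 2). Both stood lower in unsorted active than in GFP− cells of that line, at 763 ± 23.9 and 1082 ± 52.4 CPM (SD, n = 2). In the RRBP1 line 12 of 13 protein genes fell and 1 (MT-ND6, −1.02) did not pass (13 over the list alone, median −1.69, camera adjusted p = 4.01e-22, adjusted p = 0.053 with an estimated correlation). MT-CO2 changed by −1.97 ± 0.07. In the MTA2 line 10 fell and 3 did not pass (10 over the list alone, median −1.23, camera adjusted p = 1.28e-05, adjusted p = 0.351 with an estimated correlation), with MT-ND5 at −1.83 ± 0.19 and MT-ND1 (−0.27), MT-ND2 (−0.52) and MT-ND6 (0.33) not passed. TFAM, which packages mtDNA, fell by −0.30 ± 0.07 and −0.44 ± 0.08.

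Did MTA2-tagged GFP+ cells show the same? The ISR and the cell cycle genes went the same way; their sizes are compared below. CHAC1 rose from 4.41 ± 0.486 to 29.4 ± 0.647 CPM (SD, n = 2, 2.73 ± 0.11, SE), TRIB3 from 33.0 ± 2.45 to 152 ± 5.22 CPM (2.20 ± 0.10), DDIT3 by 1.58 ± 0.10, ATF3 by 1.34 ± 0.14 and ATF4 from 339 ± 7.58 to 573 ± 4.58 CPM (0.76 ± 0.06; adjusted p = 4.47e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 19 ISR regulators 17 rose, 0 fell and 2 did not pass (18 over the list alone, median 1.18, camera adjusted p = 2.24e-20, adjusted p = 0.0401 with an estimated correlation). Of 18 amino acid genes 13 rose, 1 fell and 4 did not pass (14 and 1 over the list alone, median 0.64, camera adjusted p = 9.06e-10, adjusted p = 0.0562 with an estimated correlation), CTH (2.48 ± 0.08) and SLC6A9 (2.35) first. ANGPTL4 (3.83 ± 0.17, 14.2-fold), PID1, H2AC6, DDIT4 and SESN2 were also among the 10 highest genes. DELE1 (0.06) and OMA1 (−0.03) did not pass.

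KIF20A fell by −3.46 ± 0.08 in MTA2-tagged GFP+ cells, beside CDC25C, DLGAP5, TOP2A, TROAP, CENPF, BUB1, CENPA, DEPDC1 and NEK2, the other lowest genes. All 28 mitosis genes were lower (28 over the list alone, median −3.12, camera adjusted p = 7.38e-183, adjusted p = 0.00661 with an estimated correlation), as were all 28 DNA replication genes (28 over the list alone, median −2.17, camera adjusted p = 1.39e-84, adjusted p = 0.000947 with an estimated correlation). CDKN1A rose from 230 ± 13.6 to 919 ± 15.7 CPM (SD, n = 2, 2.00 ± 0.10, SE). Of 27 p53 targets 23 rose, 1 fell and 3 did not pass (23 and 1 over the list alone, median 0.78, camera adjusted p = 5.84e-17, adjusted p = 0.00661 with an estimated correlation). Of 23 cholesterol synthesis genes 18 fell, 1 rose and 4 did not pass (19 and 1 over the list alone, median −0.66, camera adjusted p = 4.65e-08, adjusted p = 0.159 with an estimated correlation).

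Inflammatory genes rose in MTA2-tagged GFP+ cells. Of 36 interferon-stimulated genes 17 rose, 1 fell and 18 did not pass (18 and 1 over the list alone, median 0.32, camera adjusted p = 0.00903, adjusted p = 0.552 with an estimated correlation), IFI44L (1.79) and IFIT1 (0.58 ± 0.09) among the risers. Those that rose numbered 11 without GFP− replicate 1 or GFP+ replicate 2 and 9 without GFP− replicate 2 or GFP+ replicate 1. ISG15 (1.09) lost its call without GFP+ replicate 1 (adjusted p = 0.0700). Of 18 NF-kB and secreted inflammatory genes 11 rose, 1 fell and 6 did not pass (11 and 1 over the list alone, median 0.56, camera adjusted p = 0.00467, adjusted p = 0.237 with an estimated correlation), CXCL2 and CXCL3 among them. Of 3 tested blood and immune cell markers 2 rose, 0 fell and 1 did not pass in the same comparison (2 over the list alone, median 0.73, camera adjusted p = 0.169), and 1 rose without GFP+ replicate 2. Across all genes 2781 were higher and 3744 lower (3947 and 2920 scaled by library totals). The sum of 6525 was 3980 without GFP+ replicate 1 and 4006 without GFP+ replicate 2.

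Did the GFP effect differ between the lines? Genes called in both lines mostly went the same way. Of 4275 genes called in both lines 1671 were higher and 2532 lower in both, against 529 and 835 due by chance, and 72 went opposite ways (1341 due). Over all shared genes r was 0.766 (genes are not independent replicates). The effect differed for 1089 of 17082 genes, higher in the MTA2 line for 260 and lower for 829 (618 and 837 without a count filter). Without one library or another 99 to 217 were higher and 493 to 758 lower. Mitosis genes fell further in the MTA2 line (difference −1.02, 28 lower, 28 over the list alone, camera adjusted p = 8.76e-79, adjusted p = 0.00467 with an estimated correlation). ATF4 (0.36, adjusted p = 0.0022), ATF3 (0.97), DDIT3 (0.39), CHAC1 (0.79) and CDKN1A (0.77) rose further there, and HSPA5 less (−0.47). TRIB3 rose alike, from 34.1 to 155 CPM in the RRBP1 and from 33.0 to 152 CPM in the MTA2 line. The ISR list differed by a median of 0.26 (camera adjusted p = 9.25e-06), not kept with an estimated correlation (adjusted p = 0.103). The effect was higher in the MTA2 line for IFIT1 (1.34), COL1A1 (1.81), EGR1 (1.53), H1-2 (1.38) and NR1D1 (1.29). It was lower there for E2F2 (−1.51), BRIP1 (−1.51), KCNK2 (−1.48) and FAM111B (−1.48). H1-2, E2F2, BRIP1 and FAM111B went the same way in both lines, but the others had opposite signs. These were IFIT1 (−0.72 in the RRBP1 and 0.58 in the MTA2 line), COL1A1 (−0.67, 1.10), EGR1 (−0.10, 1.39), NR1D1 (−0.28, 0.98) and KCNK2 (0.05, −1.46). The count was 596 without RRBP1 GFP− replicate 2, the lowest, and 975 without MTA2 GFP− replicate 2, the highest.

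**Figure D3:**
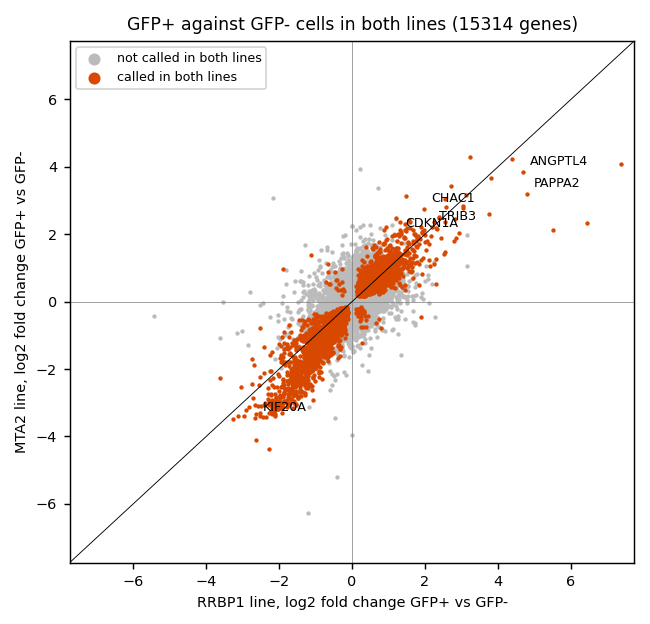
Log2 fold change of GFP+ against GFP− cells in the RRBP1 and MTA2 lines for each gene tested in both.

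Within a line, the ApaLI effect and the GFP effect share no library. Their fold changes correlated at r = 0.143 in the RRBP1 line and 0.229 in the MTA2 line (genes are not independent replicates). Of 1186 genes called in both comparisons of the RRBP1 line 74.5% went the same way, and of 390 in the MTA2 line 75.6% did; CDKN1A and RRM2B rose in both comparisons of both lines. The r of the RRBP1 line was 0.266 over genes with at least 5 mean CPM and 0.0943 without active replicate 1. Of the 56 list calls made by camera in the 4 main comparisons, 16 were kept with an estimated correlation between genes.

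**Figure D4:**
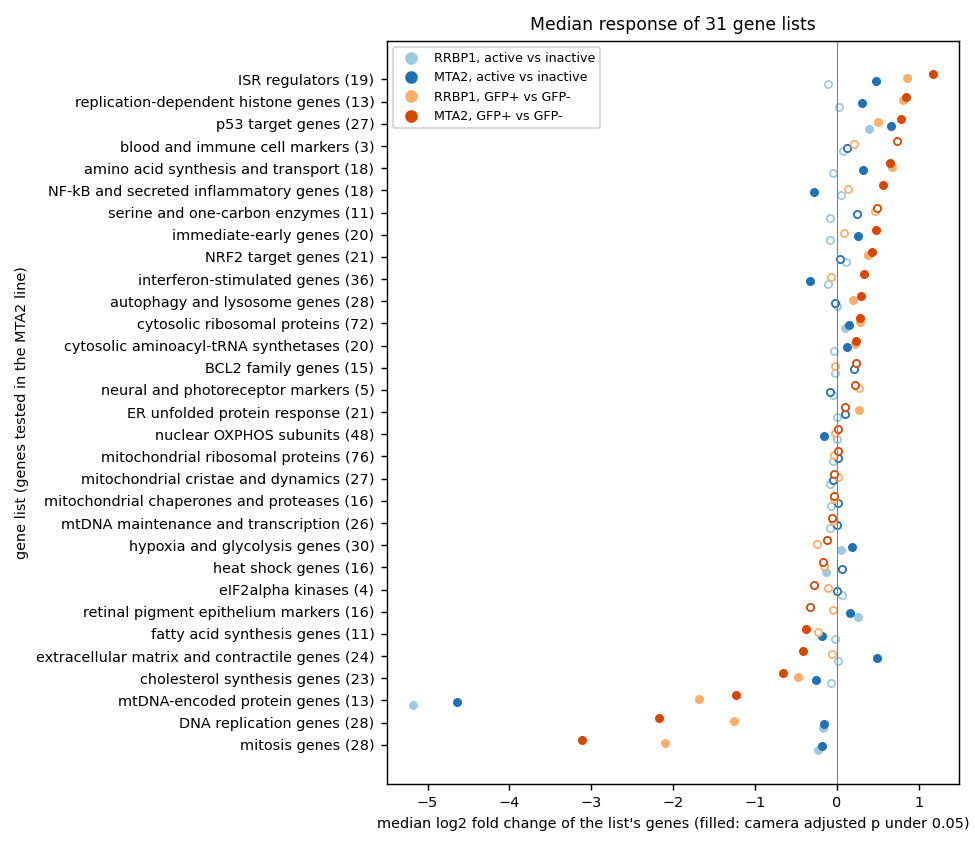
Median log2 fold change of 31 gene lists in the main comparisons, filled where camera passed; 15 lists near 0 in unsorted RRBP1-tagged cells turn direction under another scaling, as do some near 0 in the other comparisons.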

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

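The bound on a whole rise by sorting and both tests of uncut cells were chosen only after the result was seen. The line differences listed first were singled out by an interaction test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or camera for lists). Their values are the MTA2 minus the RRBP1 log2 fold change. The ISR, mitosis and mtDNA patterns after them lie within each line.

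The ApaLI effect differed for 414 genes. The highest were MMP2 (2.05), CHAC1 (1.97), SLC6A9 (1.75), IGFBP5 (1.71) and TAGLN (1.56); MMP2 lost its call without any one of 5 libraries. The lowest were HSD17B2 (−2.41), PCDH7 (−2.17), SLC7A8 (−2.06), RIMS1 (−1.79) and SULT1C2 (−1.78). TRIB3 differed by 0.98 and CDKN1A by 0.51. Lists whose difference camera also kept with an estimated correlation were ISR regulators (0.51), amino acid synthesis and transport (0.29) and extracellular matrix and contractile genes (0.49). Lists not kept with it were serine and one-carbon enzymes (0.29), cytosolic aminoacyl-tRNA synthetases (0.11), interferon-stimulated genes (−0.34), NF-kB and secreted inflammatory genes (−0.29), mtDNA-encoded protein genes (0.56), nuclear OXPHOS subunits (−0.16), mitochondrial ribosomal proteins (0.0759), p53 target genes (0.14), replication-dependent histone genes (0.54), cholesterol synthesis genes (−0.25), fatty acid synthesis genes (−0.17), hypoxia and glycolysis genes (0.11), immediate-early genes (0.34) and heat shock genes (0.16).

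The GFP effect differed for 1089 genes. COL1A1 (1.81), EGR1 (1.53), H1-2 (1.38), IFIT1 (1.34) and NR1D1 (1.29) were highest and PAPPA2 (−1.56), E2F2 (−1.51), BRIP1 (−1.51), KCNK2 (−1.48) and FAM111B (−1.48) lowest; PAPPA2 lost its call without MTA2 GFP− replicate 1 or RRBP1 GFP− replicate 2. ATF4 differed by 0.36, ATF3 by 0.97, DDIT3 by 0.39, CHAC1 by 0.79, HSPA5 by −0.47 and CDKN1A by 0.77. Lists kept with an estimated correlation were p53 target genes (0.38), mitosis genes (−1.02) and DNA replication genes (−0.87). Lists not kept were ISR regulators (0.26), ER unfolded protein response (−0.21), interferon-stimulated genes (0.40), mtDNA-encoded protein genes (0.39), mitochondrial ribosomal proteins (0.0785), cholesterol synthesis genes (−0.21), fatty acid synthesis genes (−0.0906), hypoxia and glycolysis genes (0.12), NRF2 target genes (0.10), immediate-early genes (0.47) and extracellular matrix and contractile genes (−0.16).

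ISR regulators rose in GFP+ against GFP− cells of both lines but not in unsorted RRBP1-tagged cells with active ApaLI. Both populations were sorted, so an effect of sorting common to both gates cancels in GFP+ against GFP− cells. In GFP− against unsorted active cells the ISR median was −0.11 in the RRBP1 and −0.0869 in the MTA2 line, with members going both ways. The 2 SE of the list's mean, taken over its 19 genes and not over libraries, were 0.39 and 0.41. The upper bounds (median plus 2 SE), 0.28 and 0.32, lie below the GFP+ medians of 0.85 and 1.18. GFP+ cells were sorted through another gate, and an effect of sorting on them alone was not measured. These bounds therefore cannot decide on sorting. Whether a small share of GFP+ cells was diluted in the unsorted culture cannot be decided. Of called ISR genes 10 of 17 in the RRBP1 and 10 of 17 in the MTA2 line had unsorted levels between the sorted ones, and 7 in each did not. A plain mixture of the gates would put called genes between them, apart from the spread between libraries. Of all called genes only 40.8% and 33.3% lay there. With a small share of GFP+ cells, however, unsorted levels would lie close to GFP− levels, where that spread can carry them outside. These percentages therefore neither show nor exclude such a mixture, and the ISR count draws no conclusion. No biological explanation was tested.

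Mitosis genes were lower in GFP+ than in GFP− cells. Were the gate only parting one culture by cell cycle, GFP− cells could be expected to gain what GFP+ cells lose. Yet against unsorted active cells the median was −0.47 (0 higher, 23 lower) in the RRBP1 and −0.83 (0 higher, 26 lower) in the MTA2 line. The 2 SE of the list's mean, taken over genes and not over libraries, were 0.09 and 0.13. Scaling between libraries left −2.06 and −3.03 at the nearest to 0. Whether sorting itself lowered mitosis genes in both gates was not tested. A biological explanation was not tested either.

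Mean levels of mtDNA protein genes stepped down from unsorted active to GFP− cells for all 13 in both lines, and on to GFP+ cells for 13 in the RRBP1 line (1 not passed) and 12 in the MTA2 line (10 passed; camera adjusted p = 0.351 with an estimated correlation). Scaling between libraries left the GFP+ against GFP− medians at −1.65 and −1.14, nearest to 0. A share of cells with uncut mtDNA in the GFP− gate could give all genes one share, but 3 of 13 in the RRBP1 and 5 of 13 in the MTA2 line lay over 2-fold from the median share (2 and 4 of the 12 with at least 1 CPM in GFP− cells). In every pairing of a GFP− with a GFP+ library 3 of these did in the MTA2 line, which met the bound set. They were MT-CO1 (120 CPM in GFP− cells), MT-ND1 (4.52 CPM) and MT-ND2 (4.19 CPM). As MT-ND1 and MT-ND2 were that low, the bound rests on MT-CO1 and does not settle the matter. In the RRBP1 line only MT-ND1 and MT-ND2 did so, at 5.62 and 6.08 CPM in GFP− cells, too few for the bound set. Uncut cells in the GFP− gate cannot be told apart in either line. Cells with uncut mtDNA in the unsorted culture that lie outside both gates remain possible: for 13 genes in the RRBP1 and 13 in the MTA2 line the share lay within 2-fold of the median (2.41% and 3.57%), a hypothesis only. The ribosomal RNAs MT-RNR1 and MT-RNR2 did not step down from unsorted active to GFP− cells (763 to 860 and 1082 to 1243 CPM in the RRBP1 line), which such cells alone leave unexplained.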

How the results depend on the processing

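Crossing the inactive replicate numbers within the block was the test here chosen only after the result was seen. All other alternatives were planned before the data were examined. Of the values that answer a comparison 126 stayed as reported and 62 moved. A count of called genes or lists stayed if its total was within 1.5 times the reported one or the reverse. Its split into higher and lower was not judged, so a split that turned under library totals can count as stayed. A correlation stayed if it kept its direction and moved by less than the spread over left-out libraries. Of the genes and lists 10801 values stayed, 881 lost their call, 292 gained one and 1 with a call turned direction. Values without a call in either setting count as stayed even where their direction turned. Of the lost calls 284 came from the added 2-fold threshold, by construction.

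Adding a 2-fold threshold lowered the genes called by construction. They numbered 142 (ApaLI), 1016 (GFP), 511 (GFP− against inactive) and 1954 (GFP+ against inactive) in the RRBP1 line, 120, 1772, 629 and 3353 in the MTA2 line, and 80 and 190 for the line differences in the ApaLI and GFP effects. Without a count filter 1727 genes were called in the MTA2 ApaLI comparison and 1180 for the line difference in it. With only the 4 libraries compared 141 were called in the MTA2 ApaLI comparison and 1513 in MTA2 GFP− against inactive, but 8459 in MTA2 GFP and 6198 in RRBP1 GFP− against inactive, more than as reported. With all 16 libraries in one fit 538 were called in the RRBP1 and 1490 in the MTA2 ApaLI comparison. For these last 3 settings the cause was not tested.

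Leaving out one library gave 703 to 1460 genes in the RRBP1 ApaLI comparison, 5151 to 5767 in RRBP1 GFP, 3362 to 3989 in RRBP1 GFP− against inactive and 7481 to 8094 in RRBP1 GFP+ against inactive. The MTA2 ranges were 160 to 3304, 3980 to 4703, 1633 to 4797 and 7065 to 9768, and the line differences 141 to 2673 (ApaLI) and 596 to 975 (GFP). In these fits the lone sample is assumed to vary like the other groups. The highest MTA2 count came without inactive replicate 1 in each of the 3 comparisons that use it. Leaving out a replicate number in all groups at once was not run, since it leaves no spread.

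Camera called 56 of 124 lists and kept 16 with an estimated correlation. Fry turned mitochondrial cristae and dynamics in RRBP1 GFP+ against GFP− cells from a median of 0.00924 to a call as lower (adjusted p = 0.0490); the cause was not tested. Between-line r over ApaLI effects was 0.588 with genes of at least 5 mean CPM, 0.179 with mtDNA genes removed and 0.285 to 0.424 leaving out one library. Between-line r over GFP effects was 0.887 at 5 CPM and 0.679 to 0.762 leaving out one library. Between the ApaLI and GFP effects r was 0.266 at 5 CPM, 0.115 without mtDNA genes and 0.0943 to 0.153 leaving out one library in the RRBP1 line, and 0.334 at 5 CPM and 0.165 to 0.256 leaving out one library in the MTA2 line. The cause was not tested.

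With the replicate number as a replicate block the counts were 1685 (ApaLI), 6740 (GFP), 5281 (GFP− against inactive) and 8844 (GFP+ against inactive) in the RRBP1 line, 416, 6100, 2822 and 8974 in the MTA2 line, 327 and 956 for the line differences, and 55 lists. Deviations of libraries that share a number correlated between −0.0200 and 0.0603 over 6 pairs of groups in the RRBP1 line and between −0.205 and 0.0608 in the MTA2 line, so the numbers do not establish pairs. Crossing the inactive numbers gave 3138 genes in MTA2 GFP− against inactive, where 3154 were called unpaired.

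Library totals alone moved the median gene by more than 0.1 in the sorted against inactive comparisons: 0.123 and 0.159 in the RRBP1 line (GFP−, GFP+) and 0.105 and 0.200 in the MTA2 line. The higher and lower counts became 4561 and 1191, 6442 and 2934, 2766 and 896, and 6751 and 3208. Of 664 gene values this scaling ended 42 calls and added 26, DESeq2 size factors ended 2 and added 4, and DESeq2's Wald test ended 14 and added 14. Depth limits what can be said of genes with few counts. Recovery of 1.5-fold changes was 43 of 100 in the MTA2 ApaLI comparison and 67 of 100 in the RRBP1 one, although the MTA2 libraries are the deeper ones; the coefficients of variation were 8.18% and 3.92%.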

Other observations

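The contrasts of GFP− cells with unsorted active cells were chosen only after the result was seen. GFP− cells also carried the p53 response against inactive ApaLI: CDKN1A was higher by 1.83 ± 0.05 (SE) in the RRBP1 and 2.26 ± 0.10 in the MTA2 line. The p53 targets had 25 higher, 1 lower and 1 not passed (25 and 1 over the list alone, median 0.71, camera adjusted p = 1.69e-31, adjusted p = 0.0137 with an estimated correlation) in the RRBP1 line and 21 higher, 0 lower and 6 not passed (21 and 0 over the list alone, median 0.88, camera adjusted p = 2.71e-35, adjusted p = 0.00224 with an estimated correlation) in the MTA2 line. Mitosis genes had 0 higher, 27 lower and 1 not passed (0 and 27 over the list alone, median −0.71, camera adjusted p = 6.44e-32, adjusted p = 0.269 with an estimated correlation) in the RRBP1 line and 27 of 28 lower in the MTA2 line (camera adjusted p = 7.82e-72, adjusted p = 0.0279 with an estimated correlation), with MKI67 at −0.52 ± 0.05 and −0.87 ± 0.09. The inflammatory gene CXCL8 was higher by 0.94 ± 0.17 and 1.19 ± 0.14, and the chaperone HSPA5 by 0.60 ± 0.05 and 1.14 ± 0.06. ISR regulators had 6 higher, 10 lower and 3 not passed (6 and 11 over the list alone, median −0.23, camera adjusted p = 0.116, adjusted p = 0.495 with an estimated correlation) in the RRBP1 line and 10 higher, 1 lower and 8 not passed (12 and 1 over the list alone, median 0.34, camera adjusted p = 5.29e-06, adjusted p = 0.144 with an estimated correlation) in the MTA2 line. TRIB3 was lower by −0.56 ± 0.06 in the RRBP1 and higher by 0.52 ± 0.10 in the MTA2 line, while DDIT3 stood at 14.9 and 19.1 CPM (inactive, GFP−) in the RRBP1 and 9.61 and 18.9 CPM in the MTA2 line. Of the tested blood and immune cell markers 1 of 2 and 1 of 3 were higher in these comparisons. In all, 2579 genes were higher and 2749 lower in the RRBP1 line and 1643 and 1511 in the MTA2 line (4561 and 1191, then 2766 and 896, scaled by library totals). The RRBP1 count of 5328 was 3362 without inactive replicate 2 and 3411 without GFP− replicate 2. The MTA2 count of 3154 was 1633 and 1685 without GFP− replicates 1 and 2 and 4797 without inactive replicate 1.

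GFP+ cells against inactive ApaLI showed CDKN1A higher by 3.10 ± 0.05 (SE, RRBP1 line) and 4.26 ± 0.11 (MTA2 line), with 4423 genes higher and 4438 lower in the RRBP1 line and 4567 and 4643 in the MTA2 line (6442 and 2934, then 6751 and 3208, scaled by library totals). Sorting and the enzyme both differ in these comparisons. Against unsorted active cells, GFP− cells had 1546 genes higher and 1508 lower in the RRBP1 line and 981 and 779 in the MTA2 line. The RRBP1 transcript changed by −0.26 in unsorted RRBP1-tagged cells with active ApaLI (adjusted p = 0.0084) and lost its call without inactive replicate 2 (0.153), without active replicate 2 (0.152) and by library totals. MTA2 (−0.04) did not pass in the MTA2 line.

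Further lists passed camera in unsorted RRBP1-tagged cells with active against inactive ApaLI. Hypoxia and glycolysis genes, NDRG1 and ALDOC among them, had 10 higher, 2 lower and 18 not passed (11 and 3 over the list alone, median 0.05, camera adjusted p = 0.00929, adjusted p = 0.630 with an estimated correlation), against 6 and 1 without inactive replicate 1, 5 and 0 without inactive replicate 2 and then 5 and 1 without active replicate 2, and lost the camera call without inactive replicate 2. Cytosolic ribosomal proteins had 21 higher, 0 lower and 51 not passed (29 and 0 over the list alone, median 0.10, camera adjusted p = 6.81e-05, adjusted p = 0.630 with an estimated correlation), against 2 and 0 without inactive replicate 1 and then 3 and 0 without inactive replicate 2 or active replicate 2. Retinal pigment epithelium markers had 6 higher, 1 lower and 6 not passed (6 and 1 over the list alone, median 0.25, camera adjusted p = 0.00716, adjusted p = 0.286 with an estimated correlation), against 3 and 0 without inactive replicate 1. Heat shock genes had 0 higher, 7 lower and 9 not passed (0 and 9 over the list alone, median −0.13, camera adjusted p = 0.0405, adjusted p = 0.630 with an estimated correlation), against 0 and 3 without inactive replicate 1 and then 0 and 2 without inactive replicate 2 or active replicate 1, and lost the camera call without either inactive replicate or active replicate 1.

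In unsorted MTA2-tagged cells with active ApaLI, hypoxia and glycolysis genes (NDRG1, VEGFA) had 6 higher, 0 lower and 24 not passed (10 and 1 over the list alone, median 0.18, camera adjusted p = 5.99e-07, adjusted p = 0.201 with an estimated correlation), against 15 and 0 without inactive replicate 1 and then 3 and 0 without active replicate 1 or active replicate 2. Aminoacyl-tRNA synthetases had 3 higher, 0 lower and 17 not passed (3 and 0 over the list alone, median 0.12, camera adjusted p = 0.00165, adjusted p = 0.201 with an estimated correlation), against 6 and 0 without inactive replicate 1, 1 and 0 without active replicate 1 and then 0 and 0 without active replicate 2. Fatty acid synthesis genes, SCD first, had 0 higher, 3 lower and 8 not passed (0 and 5 over the list alone, median −0.18, camera adjusted p = 0.000565, adjusted p = 0.0924 with an estimated correlation), against 1 and 6 without inactive replicate 1 and then 0 and 1 without active replicate 1 or active replicate 2. Nuclear OXPHOS subunits had 0 higher, 2 lower and 46 not passed (0 and 9 over the list alone, median −0.16, camera adjusted p = 2.82e-05, adjusted p = 0.312 with an estimated correlation), against 5 and 18 without inactive replicate 1, 0 and 4 without active replicate 1 and then 0 and 0 without active replicate 2. Mitosis genes had 0 higher, 1 lower and 27 not passed (0 and 2 over the list alone, median −0.19, camera adjusted p = 3.09e-06, adjusted p = 0.312 with an estimated correlation), against 0 and 17 without inactive replicate 1 and then 0 and 0 without inactive replicate 2, active replicate 1 or active replicate 2. DNA replication genes had 0 higher, 1 lower and 27 not passed (0 and 4 over the list alone, median −0.16, camera adjusted p = 0.00271, adjusted p = 0.106 with an estimated correlation), against 3 and 9 without inactive replicate 1 and then 0 and 0 without inactive replicate 2, active replicate 1 or active replicate 2. Cytosolic ribosomal proteins had 1 higher, 0 lower and 71 not passed (0 and 0 over the list alone, median 0.14, camera adjusted p = 6.72e-08, adjusted p = 0.194 with an estimated correlation), against 26 and 0 without inactive replicate 1 and then 0 and 0 without inactive replicate 2 or active replicate 2.

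Of that comparison's lists that lost the camera call without a library, replication-dependent histone genes had 2 higher, 0 lower and 11 not passed (4 and 0 over the list alone, median 0.30, camera adjusted p = 0.00809, adjusted p = 0.337 with an estimated correlation), against 1 and 0 without inactive replicate 2 or active replicate 1 and then 0 and 0 without active replicate 2. NF-kB and secreted inflammatory genes had 1 higher, 4 lower and 13 not passed (1 and 7 over the list alone, median −0.28, camera adjusted p = 0.0137, adjusted p = 0.276 with an estimated correlation), against 1 and 0 without active replicate 1 and then 0 and 0 without active replicate 2, with a mean of −0.03. Immediate-early genes had 2 higher, 0 lower and 18 not passed (10 and 2 over the list alone, median 0.26, camera adjusted p = 0.0185, adjusted p = 0.431 with an estimated correlation), against 10 and 1 without inactive replicate 1, 0 and 0 without active replicate 1 and then 0 and 1 without active replicate 2. Retinal pigment epithelium markers had 2 higher, 0 lower and 14 not passed (4 and 1 over the list alone, median 0.16, camera adjusted p = 0.0442, adjusted p = 0.201 with an estimated correlation), against 5 and 1 without inactive replicate 1, 1 and 1 without inactive replicate 2 and then 0 and 0 without active replicate 1 or active replicate 2.

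In GFP+ against GFP− cells of the RRBP1 line, histone genes (H2AC6, H2BC21) had 5 higher, 0 lower and 4 not passed (6 and 0 over the list alone, median 0.80, camera adjusted p = 0.00281, adjusted p = 0.0868 with an estimated correlation). In poly(A)-selected libraries these counts do not measure total histone RNA. Cholesterol synthesis genes, INSIG1 and HMGCS1 among them, had 1 higher, 16 lower and 6 not passed (1 and 16 over the list alone, median −0.47, camera adjusted p = 4.93e-05, adjusted p = 0.435 with an estimated correlation). Autophagy and lysosome genes, MAP1LC3B and WIPI1 among them, had 17 higher, 1 lower and 10 not passed (17 and 1 over the list alone, median 0.19, camera adjusted p = 4.12e-05, adjusted p = 0.0461 with an estimated correlation). Cytosolic ribosomal proteins had 68 higher, 0 lower and 4 not passed (70 and 0 over the list alone, median 0.28, camera adjusted p = 8.3e-14, adjusted p = 0.0868 with an estimated correlation).

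MTA2-tagged GFP+ cells had aminoacyl-tRNA synthetases at 10 higher, 1 lower and 9 not passed (10 and 1 over the list alone, median 0.24, camera adjusted p = 4.32e-05, adjusted p = 0.145 with an estimated correlation). Histone genes had 7 higher, 1 lower and 5 not passed (7 and 1 over the list alone, median 0.84, camera adjusted p = 0.000298, adjusted p = 0.257 with an estimated correlation). Here too the counts do not measure total histone RNA. Fatty acid synthesis genes had 2 higher, 7 lower and 2 not passed (2 and 7 over the list alone, median −0.38, camera adjusted p = 0.0294, adjusted p = 0.183 with an estimated correlation). NRF2 targets, ABCC3 and HMOX1 among them, had 11 higher, 1 lower and 9 not passed (11 and 1 over the list alone, median 0.42, camera adjusted p = 5.61e-05, adjusted p = 0.131 with an estimated correlation). Autophagy and lysosome genes had 14 higher, 1 lower and 13 not passed (14 and 1 over the list alone, median 0.30, camera adjusted p = 0.00418, adjusted p = 0.110 with an estimated correlation), against 8 and 0 without GFP+ replicate 2. Cytosolic ribosomal proteins had 43 higher, 0 lower and 29 not passed (47 and 0 over the list alone, median 0.28, camera adjusted p = 6.67e-06, adjusted p = 0.230 with an estimated correlation), against 16 and 0 without GFP− replicate 1, 25 and 0 without GFP− replicate 2, 19 and 0 without GFP+ replicate 1 and then 11 and 0 without GFP+ replicate 2. Immediate-early genes (KLF4, EGR1) had 10 higher, 2 lower and 8 not passed (11 and 2 over the list alone, median 0.48, camera adjusted p = 0.000751, adjusted p = 0.351 with an estimated correlation). Matrix genes, THBS1 and LOXL2 among them, had 4 higher, 15 lower and 5 not passed (5 and 15 over the list alone, median −0.42, camera adjusted p = 0.00383, adjusted p = 0.110 with an estimated correlation).

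The other lists did not pass camera in unsorted RRBP1-tagged cells. Another scaling turns the median of serine and one-carbon enzymes, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, mitochondrial chaperones and proteases, ER unfolded protein response, nuclear OXPHOS subunits, mitochondrial ribosomal proteins, mtDNA maintenance and transcription and mitochondrial cristae and dynamics. The higher or lower counts moved over 1.5 times without one library or another for serine and one-carbon enzymes, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, ER unfolded protein response, interferon-stimulated genes, NF-kB and secreted inflammatory genes, nuclear OXPHOS subunits, mitochondrial ribosomal proteins and mitochondrial cristae and dynamics. Serine and one-carbon enzymes had 0 higher, 2 lower and 9 not passed (0 and 3 over the list alone, median −0.08, adjusted p = 0.416), and amino acid synthesis and transport had 0 higher, 4 lower and 14 not passed (0 and 6 over the list alone, median −0.05, adjusted p = 0.224). Cytosolic aminoacyl-tRNA synthetases had 1 higher, 3 lower and 16 not passed (1 and 3 over the list alone, median −0.03, adjusted p = 0.816), and mitochondrial chaperones and proteases had 0 higher, 3 lower and 13 not passed (0 and 3 over the list alone, median −0.07, adjusted p = 0.258). ER unfolded protein response had 3 higher, 0 lower and 18 not passed (4 and 1 over the list alone, median −0.00183, adjusted p = 0.966, mean −0.01, test up), and interferon-stimulated genes had 2 higher, 2 lower and 26 not passed (2 and 2 over the list alone, median −0.11, adjusted p = 0.832). NF-kB and secreted inflammatory genes had 1 higher, 1 lower and 13 not passed (1 and 1 over the list alone, median 0.04, adjusted p = 0.805), and nuclear OXPHOS subunits had 0 higher, 1 lower and 47 not passed (0 and 1 over the list alone, median −0.00303, adjusted p = 0.983). Mitochondrial ribosomal proteins had 1 higher, 3 lower and 72 not passed (1 and 1 over the list alone, median −0.05, adjusted p = 0.399), and mtDNA maintenance and transcription had 1 higher, 3 lower and 22 not passed (1 and 3 over the list alone, median −0.09, adjusted p = 0.737). Mitochondrial cristae and dynamics had 0 higher, 1 lower and 26 not passed (0 and 0 over the list alone, median −0.09, adjusted p = 0.461).

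Nor did these lists pass in unsorted RRBP1-tagged cells. Another scaling turns the median of cholesterol synthesis genes, fatty acid synthesis genes, autophagy and lysosome genes, BCL2 family genes, immediate-early genes and neural and photoreceptor markers. Without one library or another the counts moved over 1.5 times for cholesterol synthesis genes, fatty acid synthesis genes, NRF2 target genes, autophagy and lysosome genes, BCL2 family genes, immediate-early genes, extracellular matrix and contractile genes and neural and photoreceptor markers. The eIF2alpha kinases had 0 higher, 0 lower and 4 not passed (0 and 0 over the list alone, median 0.06, adjusted p = 0.805), and replication-dependent histone genes had 0 higher, 0 lower and 9 not passed (0 and 0 over the list alone, median 0.03, adjusted p = 0.832). Cholesterol synthesis genes had 2 higher, 1 lower and 20 not passed (2 and 1 over the list alone, median −0.07, adjusted p = 0.815), and fatty acid synthesis genes had 0 higher, 2 lower and 9 not passed (1 and 2 over the list alone, median −0.02, adjusted p = 0.816). NRF2 target genes had 5 higher, 0 lower and 16 not passed (7 and 0 over the list alone, median 0.11, adjusted p = 0.0729), and autophagy and lysosome genes had 2 higher, 0 lower and 26 not passed (2 and 0 over the list alone, median −0.000939, adjusted p = 0.816, mean 0.04, test up). BCL2 family genes had 3 higher, 0 lower and 11 not passed (4 and 0 over the list alone, median −0.03, adjusted p = 0.761, mean 0.11, test up), and immediate-early genes had 2 higher, 4 lower and 14 not passed (3 and 5 over the list alone, median −0.09, adjusted p = 0.737). Extracellular matrix and contractile genes had 3 higher, 6 lower and 14 not passed (5 and 6 over the list alone, median 0.01, adjusted p = 0.983, mean −0.17, test down), and blood and immune cell markers had 0 higher, 0 lower and 2 not passed (0 and 0 over the list alone, median 0.07, adjusted p = 0.966). Neural and photoreceptor markers had 1 higher, 1 lower and 2 not passed (1 and 1 over the list alone, median −0.05, adjusted p = 0.832).

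In unsorted MTA2-tagged cells these lists did not pass. Another scaling turns the median of mitochondrial chaperones and proteases, mtDNA maintenance and transcription, eIF2alpha kinases and autophagy and lysosome genes. Counts that moved over 1.5 times without one library or another were those of serine and one-carbon enzymes, ER unfolded protein response, mtDNA maintenance and transcription, NRF2 target genes, autophagy and lysosome genes, BCL2 family genes and heat shock genes. Serine and one-carbon enzymes had 2 higher, 0 lower and 9 not passed (5 and 3 over the list alone, median 0.25, adjusted p = 0.0536), and mitochondrial chaperones and proteases had 0 higher, 0 lower and 16 not passed (0 and 0 over the list alone, median 0.01, adjusted p = 0.845). ER unfolded protein response had 2 higher, 0 lower and 19 not passed (3 and 1 over the list alone, median 0.09, adjusted p = 0.0626), and mitochondrial ribosomal proteins had 0 higher, 0 lower and 76 not passed (0 and 0 over the list alone, median 0.01, adjusted p = 0.245). The mtDNA maintenance and transcription genes had 1 higher, 1 lower and 24 not passed (1 and 1 over the list alone, median −0.00333, adjusted p = 0.754, mean 0.04, test up), and mitochondrial cristae and dynamics had 0 higher, 0 lower and 27 not passed (0 and 0 over the list alone, median −0.05, adjusted p = 0.337). The eIF2alpha kinases had 0 higher, 0 lower and 4 not passed (1 and 1 over the list alone, median −0.00203, adjusted p = 0.889), and NRF2 target genes had 2 higher, 0 lower and 19 not passed (2 and 0 over the list alone, median 0.04, adjusted p = 0.0744). Autophagy and lysosome genes had 0 higher, 1 lower and 27 not passed (0 and 2 over the list alone, median −0.03, adjusted p = 0.337), and BCL2 family genes had 3 higher, 1 lower and 11 not passed (4 and 2 over the list alone, median 0.21, adjusted p = 0.104). Heat shock genes had 0 higher, 1 lower and 15 not passed (0 and 1 over the list alone, median 0.06, adjusted p = 0.754), and blood and immune cell markers had 0 higher, 0 lower and 3 not passed (0 and 0 over the list alone, median 0.12, adjusted p = 0.889, mean −0.03, test up). Neural and photoreceptor markers had 0 higher, 0 lower and 5 not passed (0 and 0 over the list alone, median −0.09, adjusted p = 0.786).

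Camera passed none of these lists in RRBP1-tagged GFP+ against GFP− cells. Another scaling turns the median of nuclear OXPHOS subunits and mitochondrial cristae and dynamics. Leaving out one library or another moved the counts over 1.5 times for interferon-stimulated genes, nuclear OXPHOS subunits, mitochondrial ribosomal proteins, mitochondrial cristae and dynamics and eIF2alpha kinases. Serine and one-carbon enzymes had 6 higher, 4 lower and 1 not passed (6 and 4 over the list alone, median 0.46, adjusted p = 0.475), and mitochondrial chaperones and proteases had 4 higher, 1 lower and 11 not passed (4 and 1 over the list alone, median −0.04, adjusted p = 0.686, mean 0.02, test up). Interferon-stimulated genes had 7 higher, 9 lower and 14 not passed (7 and 9 over the list alone, median −0.08, adjusted p = 0.952, mean 0.03, test up), and NF-kB and secreted inflammatory genes had 8 higher, 3 lower and 4 not passed (8 and 3 over the list alone, median 0.14, adjusted p = 0.140). Nuclear OXPHOS subunits had 5 higher, 10 lower and 33 not passed (3 and 8 over the list alone, median −0.02, adjusted p = 0.995, mean −0.02, test up), and mitochondrial ribosomal proteins had 8 higher, 13 lower and 55 not passed (4 and 11 over the list alone, median −0.04, adjusted p = 0.995). The mtDNA maintenance and transcription genes had 5 higher, 10 lower and 11 not passed (6 and 10 over the list alone, median −0.05, adjusted p = 0.779), and mitochondrial cristae and dynamics had 4 higher, 6 lower and 17 not passed (4 and 5 over the list alone, median 0.01, adjusted p = 0.986, mean −0.01, test up). The eIF2alpha kinases had 0 higher, 2 lower and 2 not passed (0 and 2 over the list alone, median −0.11, adjusted p = 0.649).

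Nor did these lists pass in RRBP1-tagged GFP+ against GFP− cells. Another scaling turns the median of BCL2 family genes. One library or another, left out, moved the counts over 1.5 times for neural and photoreceptor markers. Fatty acid synthesis genes had 2 higher, 6 lower and 3 not passed (2 and 8 over the list alone, median −0.24, adjusted p = 0.240), and hypoxia and glycolysis genes had 5 higher, 19 lower and 6 not passed (5 and 19 over the list alone, median −0.24, adjusted p = 0.0769). BCL2 family genes had 4 higher, 3 lower and 7 not passed (4 and 4 over the list alone, median −0.03, adjusted p = 0.520, mean 0.06, test up), and immediate-early genes had 7 higher, 3 lower and 10 not passed (7 and 3 over the list alone, median 0.08, adjusted p = 0.256). Heat shock genes had 2 higher, 8 lower and 6 not passed (2 and 8 over the list alone, median −0.16, adjusted p = 0.267), and extracellular matrix and contractile genes had 5 higher, 11 lower and 7 not passed (5 and 11 over the list alone, median −0.06, adjusted p = 0.0605). Retinal pigment epithelium markers had 5 higher, 4 lower and 4 not passed (5 and 5 over the list alone, median −0.05, adjusted p = 0.893, mean 0.01, test up), and blood and immune cell markers had 0 higher, 0 lower and 2 not passed (0 and 0 over the list alone, median 0.21, adjusted p = 0.952). Neural and photoreceptor markers had 2 higher, 1 lower and 1 not passed (2 and 1 over the list alone, median 0.26, adjusted p = 0.779).

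Nor did camera pass these in MTA2-tagged GFP+ against GFP− cells. Another scaling turns the median of mitochondrial chaperones and proteases, mtDNA maintenance and transcription and mitochondrial cristae and dynamics. Also moved over 1.5 times without one library or another were the counts of nuclear OXPHOS subunits, mitochondrial ribosomal proteins, mitochondrial cristae and dynamics, eIF2alpha kinases and heat shock genes. Serine and one-carbon enzymes had 6 higher, 4 lower and 1 not passed (6 and 4 over the list alone, median 0.48, adjusted p = 0.932, mean −0.02, test down), and mitochondrial chaperones and proteases had 2 higher, 3 lower and 11 not passed (2 and 3 over the list alone, median −0.04, adjusted p = 0.999). ER unfolded protein response had 6 higher, 5 lower and 10 not passed (6 and 5 over the list alone, median 0.10, adjusted p = 0.234), and nuclear OXPHOS subunits had 1 higher, 4 lower and 43 not passed (1 and 1 over the list alone, median 0.01, adjusted p = 0.707). Mitochondrial ribosomal proteins had 6 higher, 7 lower and 63 not passed (4 and 3 over the list alone, median 0.01, adjusted p = 0.561), and mtDNA maintenance and transcription had 1 higher, 6 lower and 19 not passed (1 and 6 over the list alone, median −0.06, adjusted p = 0.464). Mitochondrial cristae and dynamics had 1 higher, 7 lower and 19 not passed (1 and 7 over the list alone, median −0.04, adjusted p = 0.999), and eIF2alpha kinases had 0 higher, 3 lower and 1 not passed (0 and 3 over the list alone, median −0.28, adjusted p = 0.332). Hypoxia and glycolysis genes had 6 higher, 9 lower and 15 not passed (6 and 9 over the list alone, median −0.12, adjusted p = 0.805, mean −0.03, test up), and BCL2 family genes had 6 higher, 3 lower and 6 not passed (6 and 3 over the list alone, median 0.24, adjusted p = 0.237). Heat shock genes had 2 higher, 5 lower and 9 not passed (2 and 7 over the list alone, median −0.17, adjusted p = 0.878), and retinal pigment epithelium markers had 4 higher, 5 lower and 7 not passed (5 and 5 over the list alone, median −0.33, adjusted p = 0.979, mean −0.17, test up). Neural and photoreceptor markers had 0 higher, 1 lower and 4 not passed (0 and 1 over the list alone, median 0.22, adjusted p = 0.978, mean −0.08, test up).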
